A study of Homo sapiens with 3 samples.

How the data were processed

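Chromatin immunoprecipitation with sequencing (ChIP-seq) recovers the DNA that a protein is bound to and locates it by sequencing. The samples were primary cultures of human endometrial stromal cells, the connective tissue cells of the uterine lining. Endogenous progesterone receptor (PGR) was silenced with siRNA for 48 h, and a flag-tagged PGR-A or PGR-B was introduced with an adenovirus for 24 h. The cells then received a differentiation cocktail of E, P and cAMP for 2 h, per the labels' protocols. Sheared chromatin was pulled down with an anti-flag affinity gel. There was 1 library for PGR-A, 1 for PGR-B and 1 input library, which the labels describe as pooled.

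Per the submitters' processing notes, reads were handled with CASAVA 1.8 and Bowtie 1, peaks were called with MACS 1.4.1, and the genome build was hg18. Per the file headers, MACS compared each ChIP library with the same input at a p cutoff of 1e-05, with an effective genome size of 2.7e+09, a band width of 300, a model fold of 5 to 30 and a local background over 1000 and 10000 bp. Per the file headers, tags were 100 bp long, at most 2 tags per position were kept, the smaller data set was scaled towards the larger, and the shift model gave d = 200 in both runs. Peaks were therefore called per library and not on pooled ChIP samples. Read trimming and mapping settings are not given in the sources used here.

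The deposited tag values are whole-number counts of tags within each peak, not scaled by the authors. The deposited fold enrichment is the caller's enrichment over the local background that MACS derived from the scaled input. It is not the tag count or the mean tag density of the whole peak divided by that background. The deposited FDR is in percent and comes from the caller's exchange of ChIP and input. The deposited score of each peak is −10 times the log10 of its MACS p-value: its column name was lost in the text file, but its lowest value equals the stated cutoff and it matches the scores in the accompanying peak list. Between both formats, 0 peaks differed in position or in score (tolerance 0.005). Fold enrichment, score and FDR are the authors' values and were used to rank and describe peaks within 1 list and to filter both lists at common cutoffs. In the closing observations, tag density was also divided by fold within the PGR-A list. This quotient was planned as an implied background, but it also depends on peak shape.

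Depth after the duplicate filter was 44373819 tags for PGR-A, 39984478 for PGR-B and 33997552 for the input, per the file headers. Chromosome Y was left out. Peaks were compared by position: a peak was shared if it overlapped a peak of the other list by at least 1 bp, and was otherwise called PGR-A-only or PGR-B-only, which means only that the other list held no called peak there. Chance overlap was taken from 1000 circular shifts of 1 list within each chromosome, whose length was set to the last peak end in either list; assembly gaps were not known to this procedure. Both lists rest on 1 input library, so unchanged libraries of the stated depths were also simulated against a common input in 400 bp windows at the caller's cutoff, 5 times, assuming an even genome. Tag density is tags per kb of peak per 1000000 filtered tags. Its ratio between libraries was taken only at overlapping pairs; the mean over all peaks of each list, called separately, is given beside it. It depends on the peak borders that the caller set in each library. Strength within a list was described by medians, interquartile ranges and the chance that a random shared peak outscores a random isoform-only peak.

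With 1 library per isoform there is no replicate spread, so no p-value was computed for any comparison. Shares carry exact Clopper-Pearson 95% intervals and tag counts exact Poisson 95% intervals. The interval of a median density ratio comes from 1000 bootstrap draws of pairs. The interval of a ratio of peak counts was derived from the exact interval of the PGR-B share of both counts. It treats the lists as independent, although most PGR-A peaks overlapped a PGR-B peak. These intervals cover counting error only, because neighbouring tags and peaks of 1 library are not independent cultures. The interval search was tested on simulated lists of 5000 peaks each: all 3000 planted overlaps were recovered, 13 of 2000 unrelated peaks overlapped by chance, and 0 results differed from a direct search. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

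The comparisons, the rule for the peaks named in the text and most alternatives were fixed before the data were examined. The named peaks are the 5 with the highest authors' fold enrichment among peaks with an FDR of at most 5% in each class; for shared peaks the rule was applied in both lists and the results joined. Alternatives were a score of at least 100, an FDR of at most 5%, a fold enrichment of at least 10, a reciprocal overlap of at least 50%, summits within 200 bp, peaks widened by 500 bp, ranking by fold enrichment, and covered base pairs in place of peak counts. Assignment of peaks to genes, gene lists and sequence motifs had been planned for an annotation of the files' own build. The table of genes at hand was of GRCh38, so coordinates were not joined to it, and genes, gene lists and motifs were not analysed here. All positions are as the deposited files give them, counted from 1.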

Results

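The data set mapped anti-flag ChIP-seq peaks for both isoforms of the progesterone receptor, a hormone-activated transcription factor, in human endometrial stromal cells. The cells were at 2 h of in vitro differentiation. PGR-A and PGR-B come from the same gene, and PGR-A lacks a segment at the amino end of PGR-B. Each isoform was introduced separately with a flag tag after siRNA treatment against the endogenous receptor. How much endogenous receptor remained is not given in the values used here. Sites were called in 1 PGR-A library of 44373819 filtered tags and in 1 PGR-B library of 39984478 filtered tags, both against 1 input library of 33997552 filtered tags. There were no replicates, so the values below describe these libraries, and intervals cover counting error only. The labels list no anti-flag pulldown from cells without a tagged receptor, so DNA recovered without the receptor was not set apart. Such DNA could add peaks to both lists and to their overlap.

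The first comparison asks how many peaks were called for each isoform. On the autosomes and chromosome X, the PGR-B list held 15108 peaks and the PGR-A list 8365, a ratio of 1.81 (95% interval 1.76 to 1.86). PGR-B peaks covered 17.2 Mb and PGR-A peaks 9.75 Mb. Peaks held 2.79% of the filtered PGR-B tags (95% interval 2.78 to 2.79) and 1.39% of the filtered PGR-A tags (1.38 to 1.39), and the mean density inside the separately called peaks was 1.62 and 1.42 tags per kb per 1000000 filtered tags. Peak widths were alike, with a median of 1051 bp (interquartile range 908 to 1256) for PGR-B and 1076 bp (933 to 1295) for PGR-A. The PGR-B library was the shallower of both. The highest authors' FDR was 1.63% in the PGR-B list and 5.16% in the PGR-A list, where 117 peaks exceeded 5%. The ratio of PGR-B to PGR-A peaks rose with stricter thresholds. With a score of at least 100 there were 6458 PGR-B and 2817 PGR-A peaks, a ratio of 2.29. With an authors' fold enrichment of at least 10 there were 2960 and 958, a ratio of 3.09.

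The second comparison asks whether the peaks of both isoforms lay at the same sites. Of the PGR-A peaks, 6518 overlapped a PGR-B peak, which is 77.9% (95% interval 77.0 to 78.8). Of the PGR-B peaks, 6538 overlapped a PGR-A peak, which is 43.3% (42.5 to 44.1). The overlapping numbers are nearly equal, so the difference between these percentages follows from the lengths of the lists. This left 1847 PGR-A-only and 8570 PGR-B-only peaks. Random circular shifts of the PGR-A list gave 1.195% of PGR-A peaks on a PGR-B peak on average and 5.22% at most, and shifts of the PGR-B list gave 0.66% of PGR-B peaks on average. Local shifts of 20 to 200 kb, chosen after the data were seen, gave 2.47% and 1.37%. In the simulation of unchanged libraries against a common input, only 18 PGR-A and 20.8 PGR-B windows were called on average and 0 in both. So few calls leave little room for overlap. The simulated genome was even and its background never fell below the genome mean, so the simulation could not test a shared-input effect. Part of the observed excess may still come from the shared input. The 6563 overlapping pairs had summits a median of 34 bp apart (interquartile range 14 to 72), and 6019 pairs, 91.7%, had summits within 200 bp of each other.

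Of the 5 shared regions with the highest fold enrichment in each list, 3 were the same, on chromosomes 20, 22 and 4. The region at chromosome 20, 45395800 to 45397059, ranked first by fold enrichment in the PGR-B list and 3rd in the PGR-A list, with summits 27 bp apart. It held 537 PGR-B tags and 376 PGR-A tags, or 10.7 and 8.02 tags per kb per 1000000 filtered tags. The region at chromosome 11, 65945353 to 65946496, ranked first in the PGR-A list and 18th in the PGR-B list. Its densities were 5.38 in PGR-A and 5.64 in PGR-B, a ratio of 1.048 whose interval included equality (0.869 to 1.26). The region at chromosome 19, 55181801 to 55182884, ranked second in the PGR-A list and 23rd in the PGR-B list, with a density ratio of 0.881 (0.725 to 1.07). The other regions named by the rule had a higher density in PGR-B. They were on chromosome 14 at 94134850 to 94135972 (ratio 2.19, interval 1.79 to 2.69) and at 75071480 to 75072752 (1.80, 1.53 to 2.13), on chromosome 22 at 41716109 to 41717601 (1.67, 1.396 to 1.99), and on chromosome 4 at 129800364 to 129802106 (1.62, 1.39 to 1.90). At the chromosome 20 region the ratio was 1.33 (1.16 to 1.52).

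Over all 6563 overlapping pairs, tag density was higher in the PGR-B library in 5754 pairs, or 87.7%. The median PGR-B to PGR-A ratio was 1.23 (95% bootstrap interval 1.22 to 1.24), with an interquartile range of 1.09 to 1.43. At least a 2-fold higher density in PGR-B was found at 167 pairs, and at least a 2-fold higher density in PGR-A at 0 pairs. The extremes, chosen after their values were seen, were a pair on chromosome 3 with a ratio of 3.48 (2.73 to 4.47), at 157801879 to 157803716 in the PGR-A list, and a pair on chromosome 6 with a ratio of 0.586 (0.387 to 0.873), at 161747213 to 161748354. The peaks of the chromosome 6 pair overlapped by only 17 bp, with the PGR-B peak at 161748338 to 161749289, so their densities belong to adjacent stretches and not to 1 site. The next lowest ratio was 0.603 (0.391 to 0.922), on chromosome 14 at 35073964 to 35074688, where the PGR-A peak lay wholly inside the PGR-B peak. Peak borders also differed at the chromosome 3 pair, which overlapped by 967 bp. Across pairs, which are not independent replicates, the densities of both libraries had a Spearman rho of 0.78.

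**Figure D1:**
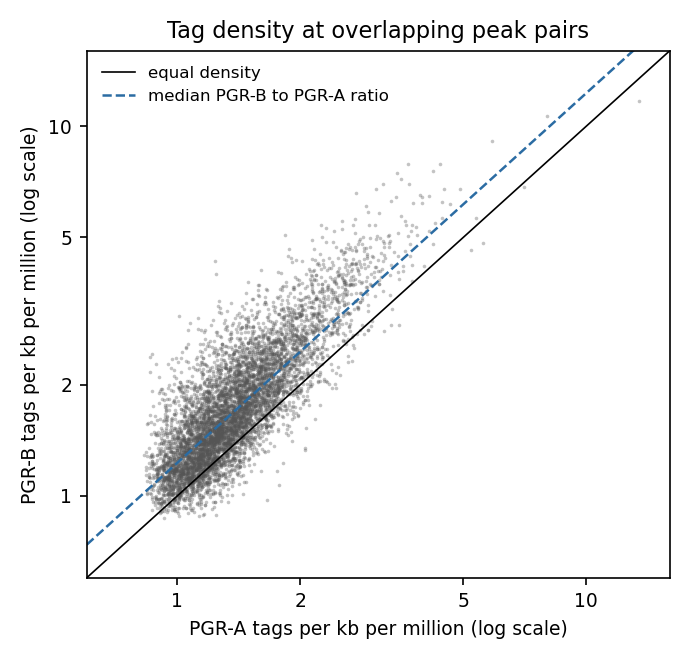
Tag density at each overlapping pair of a PGR-A peak (horizontal axis) and a PGR-B peak (vertical axis), in tags per kb per 1000000 filtered tags on log scales; each point is 1 of 6563 pairs, the solid line marks equal density and the dashed line the median ratio of 1.23. Most points, 87.7%, lie above the line of equal density.

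The third comparison asks how peaks found in both lists differed from peaks found in 1 list. Shared peaks were stronger than isoform-only peaks within each list. In the PGR-A list the median authors' fold enrichment was 6.13 (interquartile range 4.96 to 8.17) at shared peaks and 4.65 (4.07 to 5.47) at PGR-A-only peaks, and the median tag count was 68 and 49. In the PGR-B list the median fold was 8.44 (6.26 to 12.8) at shared and 5.85 (4.86 to 7.14) at PGR-B-only peaks, and the median tag count was 82 and 51. A random shared peak outscored a random isoform-only peak with a chance of 77.1% in the PGR-A list and 81.3% in the PGR-B list.

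The shared part was larger in each stronger quintile of both lists. Because the PGR-B list is longer, its shares of the full list are lower. In the weakest quintile by score, 56.1% of PGR-A peaks (53.7 to 58.5) and 14.6% of PGR-B peaks (13.4 to 15.9) were shared. In the strongest quintile, 99.5% of PGR-A peaks (99.1 to 99.8) and 89.9% of PGR-B peaks (88.8 to 91.0) were shared. In that quintile, 8 of the 1673 PGR-A peaks had no PGR-B peak and 304 of the 3022 PGR-B peaks had no PGR-A peak. With both lists cut to their 8365 strongest peaks, an alternative chosen after the data were seen, the weakest quintiles shared 34.5% for PGR-A (32.2 to 36.8) and 33.8% for PGR-B (31.6 to 36.2), and the strongest 98.4% (97.7 to 99.0) and 96.7% (95.7 to 97.5). When both lists were restricted to their 1000 strongest peaks, 68.4% of the PGR-A peaks (65.4 to 71.3) overlapped one of the PGR-B peaks. Against the full other list, 99.9% of these PGR-A peaks and 98.9% of these PGR-B peaks overlapped a peak. The lower share among the 1000 strongest thus reflects mostly rank and not a missing call. With 8365 peaks in each list the share was 62.7% (61.7 to 63.7) for both isoforms.

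**Figure D2:**
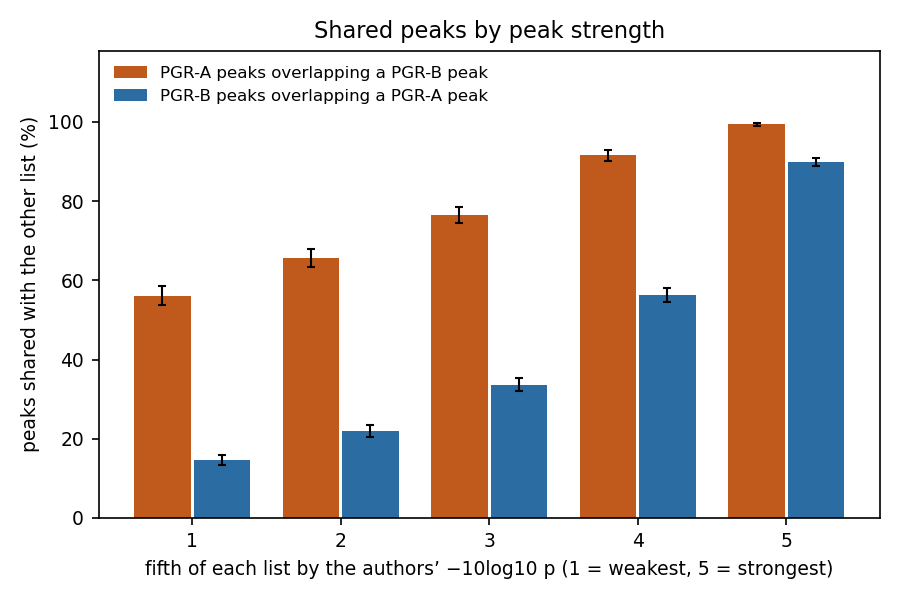
Percentage of peaks that overlap a peak of the other list by at least 1 bp (vertical axis), by quintile of the authors' −10log10 p within each list (horizontal axis, weakest to strongest); bars are PGR-A peaks (orange) and PGR-B peaks (blue), and error bars are exact 95% binomial intervals. The shares go from 56.1% to 99.5% for PGR-A and from 14.6% to 89.9% for PGR-B, whose list is the longer one.

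The 5 strongest PGR-B-only peaks ranked between 13 and 540 of 15108 by fold enrichment. Of the 5 strongest PGR-A-only peaks, 1 ranked 9 of 8365 and the others between 785 and 1097. The strongest PGR-B-only peak was on chromosome 11 at 100437946 to 100439096, with 251 tags (95% interval 221 to 284), an authors' fold of 51.7 and rank 13 of the list; the nearest PGR-A peak was 124 kb away. A further PGR-B-only peak named by the rule lay 64.6 kb from it, at 100503701 to 100505161, with 147 tags (124 to 173) and a fold of 23.9. At both chromosome 11 peaks, binding of PGR-B and reads from the introduced construct could not be told apart here. The others were on chromosome 7 at 47812414 to 47813452 (116 tags, 95.9 to 139) and at 148556722 to 148557400 (96 tags, 77.8 to 117), and on chromosome 8 at 49723941 to 49724791 (77 tags, 60.8 to 96.2). The chromosome 8 peak had a PGR-A peak only 1.11 kb away, while the nearest PGR-A peak to the one at 148556722 on chromosome 7 was 1088 kb away.

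**Figure D3:**
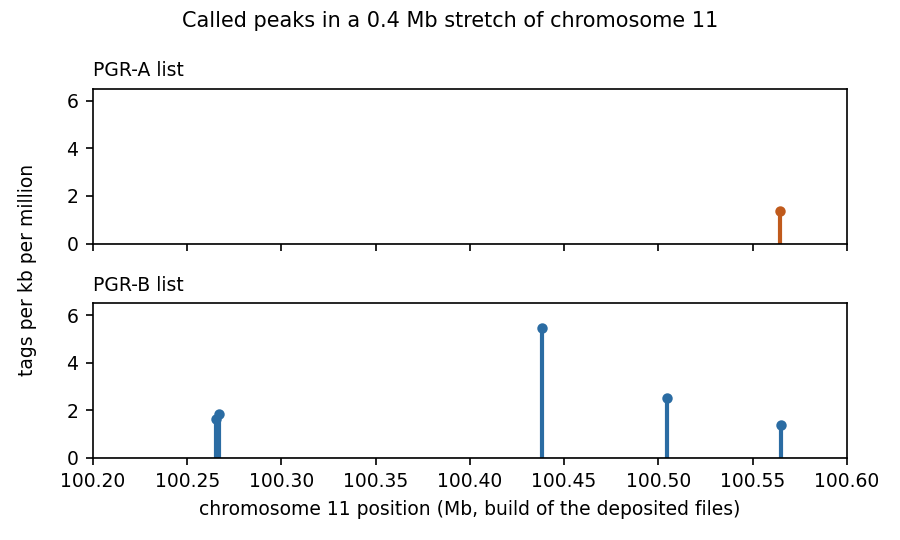
Called peaks on a 0.4 Mb stretch of chromosome 11 around the strongest PGR-B-only peak, with position in Mb on the horizontal axis and tags per kb per 1000000 filtered tags on the vertical axis; each stem is 1 peak drawn at its summit, PGR-A list above and PGR-B list below. The PGR-B list has 5 peaks here, the tallest at 5.45 and the next at 2.52 tags per kb per 1000000 filtered tags, and the PGR-A list has 1. For the tallest and the next, binding and reads from the introduced construct could not be told apart.

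The strongest PGR-A-only peak was on chromosome 2 at 32994700 to 32995156, with 142 tags (120 to 167), an authors' fold of 37.6 and rank 9 of the PGR-A list. The nearest PGR-B peak was 21.5 kb away. It was 457 bp wide, and only 10 PGR-A peaks were narrower. The next PGR-A-only peak, on chromosome 15 at 64031618 to 64032442, had 54 tags (40.6 to 70.5), a fold of 10.7 and rank 785. The remaining ones were on chromosome 19 at 50702051 to 50702788 (43 tags, 31.1 to 57.9), chromosome 5 at 175970639 to 175971683 (53 tags, 39.7 to 69.3) and chromosome 1 at 98286154 to 98287081 (57 tags, 43.2 to 73.9). Tag counts of the other library at isoform-only peaks are not in the values used here, so the lists do not show that the other isoform was absent from these sites.

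The last comparison asks whether the isoforms were spread differently over the chromosomes. The counting intervals of both shares overlapped on each of the 23 chromosomes compared. Most PGR-A peaks overlapped a PGR-B peak, so similar shares follow in part from common sites. The PGR-A share lay just outside the PGR-B interval on chromosomes 10 and 17, where it was higher, and on chromosome 4, where it was lower; the difference itself was not tested. Chromosome 2 held the largest share of both lists, with 9.55% of PGR-A peaks (8.93 to 10.2) and 9.33% of PGR-B peaks (8.87 to 9.81). The widest gap was on chromosome 10, with 5.61% of PGR-A peaks (5.12 to 6.12) and 5.21% of PGR-B peaks (4.86 to 5.58); with a fold enrichment of at least 10 the order turned, at 5.53% and 5.54%. The ratio of PGR-B to PGR-A peaks ranged from 1.58 on chromosome 21 to 1.93 on chromosome 4, so each chromosome carried more PGR-B than PGR-A peaks.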

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

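Choices were fixed before the data were examined, except the local shifts, the cut to equal list length and the alternatives for the density ratio, which were chosen after seeing the data. The FDR limit of 5% removed 117 PGR-A peaks and no PGR-B peak; counts stayed within 1.5 times and shares and ratios within their 95% intervals. A score of at least 100 left 2817 PGR-A and 6458 PGR-B peaks (ratio 2.29), of which 89.6% and 39.1% were shared. A fold enrichment of at least 10 left 958 and 2960 peaks (ratio 3.09), of which 95.5% and 30.9% were shared. The shared percentages for PGR-A and PGR-B were 76.2% and 42.2% with a reciprocal overlap of at least 50%, 72.0% and 39.8% with summits within 200 bp, and 78.9% and 44.6% with peaks widened by 500 bp. With both lists cut to 8365 peaks, 62.7% were shared from either side. The overlap of the 1000 strongest peaks stayed within its counting interval under each overlap rule and under ranking by fold (67.5% to 69.7%); a fold enrichment of at least 10 left too few PGR-A peaks for it. The intervals of the chromosome shares overlapped under each threshold, but stricter thresholds leave fewer peaks and wider intervals, which makes overlap easier. The median density ratio was 1.24 at pairs with summits within 200 bp and 1.29 as tags per peak, not divided by width. Local shifts of 20 to 200 kb put the chance overlap at 2.47% of PGR-A and 1.37% of PGR-B peaks. Of all alternative values for the main results, 15 stayed within their limits and 20 moved. Among the other values, 31 stayed and 15 moved. Some values in both tallies stayed by construction. The score and FDR filters left the strongest peaks by score unchanged, and the FDR filter removed no PGR-B peak. The limits were mostly 95% intervals, with 1.5 times for peak counts and the interquartile range for widths. Local shifts were counted as moved without such a check. The chromosome 10 share was higher for PGR-A over all peaks and lower with a fold enrichment of at least 10 (5.53% against 5.54%); the cause was not tested. With a single library per isoform, no spread between cultures can be estimated. No paired analysis was possible because each group has 1 library. Gene locations and gene lists, with their alternative windows, were not run for want of an annotation in the files' build.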

Other observations

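Tests of the sequencing depth and of the chromosome 11 peaks were chosen after the values were seen; the other tests of explanations were written down before the overlap was computed. Peaks of both isoforms were clustered. Of the PGR-B peaks, 27.8% had another PGR-B summit within 10 kb, against 9.90% on average when the peaks were placed at random on the same chromosomes, and for PGR-A the shares were 19.9% and 5.65%. Windows of 1 Mb were ranked by the sum of PGR-A and PGR-B peaks, after their values were seen. The window from 95 to 96 Mb of chromosome 5 held 22 PGR-A and 31 PGR-B peaks, and 17 of these PGR-A peaks were shared; it was the densest window of each list taken alone. It was followed by 172 to 173 Mb of chromosome 5 (18 and 30 peaks), 109 to 110 Mb of chromosome 13 (20 and 27), 134 to 135 Mb of chromosome 8 (17 and 28) and 8 to 9 Mb of chromosome 1 (17 and 27). In 100 random placements the densest window held at most 15 PGR-A or 21 PGR-B peaks. The random placements did not avoid assembly gaps or regions of low mappability, and a site split by the caller counts as neighbours. They therefore do not show how much of the clustering belongs to receptor binding.

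Isoform-only peaks, which by construction do not overlap, were tested for a common regional pattern. Of the 1847 PGR-A-only peaks, 1744 (94.4%) lay in a 1 Mb window with a PGR-B-only peak, against 1400 on average and 1483 at most in 1000 circular shifts. This is consistent with the hypothesis that sites called in 1 list lie in the same broad regions as sites called in the other. The shifts also move peaks into assembly gaps, which lowers the chance value, and regional mappability was not separated from regional binding.

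The larger number of PGR-B peaks was weighed against technical explanations. Deeper sequencing is argued against, since the PGR-B library had 0.901 times the filtered tags of the PGR-A library. An excess confined to weak calls near the threshold is argued against too. The ratio of PGR-B to PGR-A peaks was 2.29 (2.19 to 2.40) at a score of at least 100 and 1.81 over all peaks. Scores also depend on the tag density of each library, so this ratio does not show how many extra PGR-B peaks are weak. Within the PGR-B list, PGR-B-only peaks made up 85.4% of the weakest score quintile and 10.1% of the strongest. A higher tag density at common sites was present, with a median ratio of 1.23 (1.22 to 1.24). It may come from a more efficient pulldown, from more tagged protein or from stronger binding of PGR-B, and no value of this design, with 1 library per isoform, separates these.

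PGR-A-only peaks were weighed next. The hypothesis that they are mostly weak calls went with the data: their share in the strongest quintile was 0.0109 times that in the weakest (0.0047 to 0.0214). Displaced peak borders are argued against as the main cause, since 84 of them (4.55%, interval 3.64 to 5.60) had a PGR-B peak within 1 kb. The planned test of a raised local background could not decide. The quotient of tag density over fold was 0.993 times that of shared peaks in the same score quintile (median over the 5 quintiles, 0.971 to 1.03). Fold is not built on the density of the whole peak, so this quotient mixes peak shape with background. The single ratios ran from 0.985 to 1.04, the latter in the strongest quintile with only 8 PGR-A-only peaks. Weak sites may therefore have missed the PGR-B threshold or be unoccupied by PGR-B, and the tag counts needed to decide were not analysed here.

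The pair of strong PGR-B-only peaks on chromosome 11 stands 64.6 kb apart. Chromosome 11 is also the chromosome that carries the PGR gene. Whether these peaks lie at the PGR gene itself was not checked, for want of gene positions in the files' build. One hypothesis, raised after the values were seen, is that reads from the introduced PGR-B construct could give such peaks. The nearest PGR-A peak was 58.3 kb from the closer of both, so the construct for PGR-A, which has most of the coding sequence in common, gave no called peak there; a peak that was not called excludes nothing. Binding of PGR-B at these sites and construct reads cannot be told apart without an annotation of the files' own build, which would show whether the peaks sit on coding exons.

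The strongest PGR-A-only peak, on chromosome 2, stood apart in shape, for a cause that was not tested. Peaks were not filtered here against regions prone to artifact signal. This peak had a width of 457 bp. The other PGR-A peaks with a score of at least 1000, among 18 in all, were at least 981 bp wide with a median of 1281 bp. Its tag density ranked 4th in the PGR-A list, and the PGR-A-only peak with the next highest score reached 180.4.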
